A study of Arabidopsis thaliana with 24 samples.

How the data were processed

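The study measured mRNA and small RNA in shoot apices and root tips of Arabidopsis rh27-2 and wild-type (Col-0) seedlings, with 24 libraries in 8 groups of 3. Every library was assigned to its group from the labels, and no column of an unknown sample was found. The mRNA files hold raw counts per locus as deposited, with no header and no summary lines, over 33341 loci. The small RNA files hold a signal in reads per 30000000 (RP30M) per the file headers, computed by the authors, and list only the miRNA entries found in a library; an entry missing from a list was taken as 0. The labels name TopHat2, HTSeq, edgeR and Bowtie2 without roles or versions, and the TAIR10 build. The strand of counting, the pooling of plants and the total behind the 30000000 reads are not given.

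Every RP30M value was a whole number of reads within 0.001 read once divided by the smallest value of its file, which gave the depth of each library. The small RNA libraries had 9355356 to 69589971 reads, of which 225283 to 1420304 were reads of listed miRNAs, and the mRNA libraries had 15603992 to 20380109 counts on 21650 to 22788 detected loci. Replicates of a group differed by more than sampling noise in every pair, so none was a copy of another. Entry names can stand for several loci with an identical mature sequence. Gene names came from the labels for RH27 and from a RefSeq table of the TAIR10.1 assembly for the rest, with 33056 loci matched. Reads of overlapping or antisense loci, which include some precursor loci, cannot be told apart in these counts.

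Genes were tested in each tissue with edgeR 4.0.16 in R 4.3.3, after filterByExpr with a minimum count of 10, TMM scaling and robust quasi-likelihood fits, and Benjamini-Hochberg adjustment at 0.05. The difference between tissues was the interaction term of a fit over the 12 mRNA libraries. Before the data were examined, 27 gene lists with 425 hand-written members and the 325 precursor loci were fixed, and each was compared with all other genes by camera of limma 3.58.1 with a preset correlation of 0.01. Calls are also given as adjusted over the list alone. For lists whose counts of that kind are not printed, they equalled the counts over all genes. None of the camera calls held with an estimated correlation.

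The fixed plan for small RNA assumed counts, and its fallback for another unit was used: limma with trend and robust settings on log2 of RP30M plus 1, for entries with at least 30 RP30M in at least 3 libraries. Adding 1 understates the change of low entries. Family values are sums over entries of a family, so they pool both arms of a precursor. Where families are set beside targets, the arms were not told apart. Where families share their listed targets, a single one stood for them. A total of 274 entries and 161 families were listed in any library. The variance prior of limma had infinite degrees of freedom for all 79 entries in shoot apices and for 123 of 125 in root tips, so those p-values rest on a variance pooled over entries. Shares of miRNA reads were compared with exact permutation tests and, where replicate numbers pair the libraries, with exact sign-flip tests on the pairs.

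The genes named were set by a rule fixed before the data were examined: RH27; in each tissue the 10 largest rises and 10 largest falls among called genes with a symbol, a mean log2 CPM of at least 1 and no overlap between groups; up to 4 members of each list by adjusted p; the 5 strongest interaction genes; and for miRNAs the 10 largest rises and falls and the 5 most abundant entries, with 5 of each for families, where rises and falls needed the same mean log2 CPM, here a mean of 60 RP30M. Further members of a list that are named to spell out a small count (ABH1, NRPD1 in shoot apices, CRN, CLV1, DRNL, KRP3, KRP4, PARP1, PSAD1, PSBO1, MIR775, MIR824, MIR162a, MIR830, MIR319b, RH7, RPL3B, VND6) the families set beside their targets, and the called entries and families of lower abundance (miR829-3p.1, miR399a and the family miR829 in shoot apices, miR8184 and miR780.1 in root tips) were chosen after their values were seen. The value of 1 list member is not reported here. A gene with no count in a group is compared with a floor of 3 counts over that group.

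Whether replicate numbers pair the samples was checked before fits were compared. Deviations from the group means were correlated between wild-type and rh27-2 libraries of the same number. The values were 0.417, 0.369 and 0.147 in the mRNA libraries of shoot apices and 0.315, 0.358 and 0.330 in the small RNA libraries of root tips. In both sets each wild-type library went best with the rh27-2 library of its own number. The numbers were therefore taken to pair samples there. The labels state no pairing, and with 3 libraries such a match can arise by chance. Values with the replicate number as a block are given where they change a call, except for the lists written after the data had been seen, which were fitted without it. With the block, 4606 genes were higher and 4312 lower in shoot apices, and 19 miRNA entries were higher and 86 lower in root tips.

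Alternatives covered other scalings (DESeq2 size factors, upper quartile, total counts), DESeq2 1.42.0, other filters, stricter thresholds, fits over all 12 libraries, the replicate block, fry and camera with an estimated correlation, and leaving out each library in turn. For miRNAs, TMM scaling, edgeR on the recovered reads, other pseudocounts and filterByExpr were added after seeing the data. The planned filter of 1 CPM in 3 libraries equals the RP30M filter used, so it was not run separately for miRNAs. The procedure was tested on simulated data: 4-fold changes were recovered in 92.9% of cases for genes in shoot apices and 99.0% in root tips, and 2-fold changes in 51.0% and 88.9%, with 11.8% and 7.50% false calls. For miRNA entries the recovery of 2-fold changes was 50.0% in shoot apices and 20.0% in root tips, and of 4-fold changes 90.0% and 100%. For families in shoot apices 21.4% of calls were false. The interaction test recovered 39.8% of 2-fold and 86.9% of 4-fold differences for genes, with 3.85% false calls, and 0% and 80.0% for miRNA entries, with 11.1% false calls. The simulation changed few features, with 100 genes 2-fold and 98 genes 4-fold of 18833 in shoot apices. In root tips it changed 10 of 125 miRNA entries for each fold. In the data 40.9% of shoot genes, 62.1% of root genes and 71.2% of root entries were called. The adjusted cutoff was therefore stricter in the simulation, and its rates do not carry over to the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.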

Results

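The effect of the rh27-2 allele of RH27, the gene AT5G65900 for a DEAD-box RNA helicase, was examined in Arabidopsis seedlings at 5 days after germination. Shoot apices and root tips of rh27-2 and of the Col-0 wild type were each profiled by small RNA sequencing and by mRNA sequencing, with 3 libraries for each of the 8 groups and 24 libraries in all. The mRNA libraries held 15603992 to 20380109 counts over 33341 loci. The small RNA libraries of root tips corresponded to 15038765 to 18490925 reads. Those of shoot apices were far less even, at 9355356, 21878400 and 69589971 reads in wild type and 53934937, 10795610 and 38049871 in rh27-2. In each tissue and assay the first principal component separated the genotypes and carried 74.7% to 89.5% of the variance. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples. Fold changes below are log2 ratios of rh27-2 to wild type, mRNA levels are TMM-scaled CPM with the SD of 3 libraries, and calls were made at an adjusted p of 0.05.

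The transcript of RH27 itself was present in every mutant library. In root tips it fell from 25.3 ± 2.02 to 14.5 ± 1.15 CPM (log2 fold change -0.80, SE 0.094; adjusted p = 8.47e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The wild-type root libraries held 26.9, 25.8 and 23.0 CPM and the mutant ones 13.3, 15.7 and 14.4 CPM. In shoot apices the values were 32.8, 26 and 30.5 CPM in wild type against 24.1, 24.8 and 22.3 CPM in rh27-2. That difference did not pass the same edgeR test (-0.33, SE 0.12; adjusted p = 0.0712), although it did without wild-type replicate 2 (-0.43, adjusted p = 0.0411) and with scaling to total counts (-0.41, adjusted p = 0.0371).

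**Figure D1:**
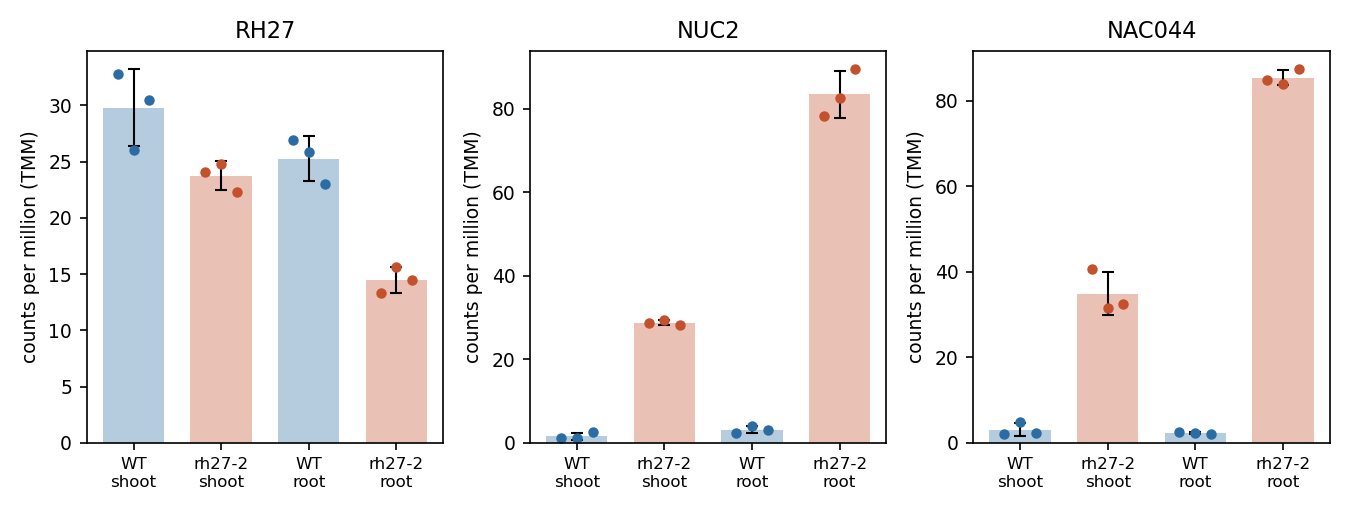
TMM-scaled CPM of RH27, NUC2 and NAC044 (vertical axes) in the 4 groups of mRNA libraries (horizontal axes). Bars are means, error bars SDs and points the 3 libraries of a group; NUC2 and NAC044 lie above every wild-type library in every mutant library of both tissues.

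In mutant shoot apices, all 8 xylem genes, 5 of 6 phloem genes and the meristem genes STM and KNAT1 rose, while 14 of 19 photosynthesis genes, 9 of 19 mitotic genes and the leaf growth regulators TCP4 and GRF1 fell. The protease gene XCP1 of maturing xylem went from 8.93 ± 1.88 to 71.0 ± 12 CPM, and the meristem gene STM from 12.5 ± 4.13 to 60.1 ± 4.40 CPM. The light-harvesting gene LHCB1.1 went from 1684 ± 480 to 172 ± 34.4 CPM. Among 18972 tested genes, 4007 were higher and 3762 lower in rh27-2 (edgeR), of which 2050 and 1550 changed at least 2-fold. Leaving out rh27-2 replicate 2 left 2531 higher and 1960 lower genes, and leaving out rh27-2 replicate 3 left 2306 lower ones. Scaling to total counts turned the balance, with 3506 higher and 4656 lower genes.

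The strongest rises among named genes in shoot apices included ICL, the isocitrate lyase of the glyoxylate cycle (5.89, from 0.543 ± 0.218 to 33.0 ± 13.0 CPM), the trehalose-phosphate phosphatase TPPD (4.47, from 2.17 ± 0.802 to 48.4 ± 7.59 CPM), the nucleolin NUC2 (4.17, from 1.59 ± 0.822 to 28.7 ± 0.630 CPM) and ATC, a homologue of TERMINAL FLOWER 1 (3.62, SE 0.22). NDB4, an alternative NADH dehydrogenase of mitochondria, rose by 4.32 and the poly(A)-binding protein PAB5 by 4.06. The cutinase CDEF1 was nearly lost (-10.46, from 476 ± 71.8 to 0.317 ± 0.162 CPM). No count of PRB1, a pathogenesis-related protein, or of CSLB06, a cellulose synthase-like protein, was found in any of the 3 mutant libraries. With 3 counts over the group as the floor, these genes were at least 397-fold and 178-fold lower, and such bounds cover counting error only. The jasmonate synthesis gene LOX2 fell from 107 ± 64.8 to 0.570 ± 0.124 CPM, and MYB23, a regulator of leaf hairs, went from 12.3 ± 4.22 to 0.0384 ± 0.0341 CPM.

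All 8 xylem and secondary wall genes tested in shoot apices rose, among them XCP1 (2.99), LAC4 (1.71), XCP2 (1.62) and CESA7 (1.37). Against other genes the list was higher with camera at a preset correlation (adjusted p = 1.73e-07), but not with an estimated correlation (adjusted p = 0.645). Of 6 phloem genes, 5 rose and none fell, including the sieve element genes SEOR1 (1.76, from 22.6 ± 2.88 to 76.6 ± 10.9 CPM) and CALS7 (1.40) and the regulator APL (1.38) (camera adjusted p = 3.25e-05; 0.391 as the adjusted p with an estimated correlation). In the photosynthesis list, 14 of 19 genes fell and none rose: the 12 light-harvesting genes with PSAD1 and PSBO1, led by LHCB1.1 (-3.30), LHCB2.1 (-1.92) and LHCA1 (-1.62) (camera adjusted p = 8.01e-06, but adjusted p = 0.905 with an estimated correlation). The Rubisco small subunit genes and RCA did not pass the test. Of 19 mitotic genes, 9 fell and none rose, for example CYCB2;3 (-1.18, from 29.7 ± 5.51 to 13.1 ± 1.75 CPM) and CDKB2;2 (-1.06) (camera adjusted p = 0.00548, but adjusted p = 0.905 with an estimated correlation). The 3 tested seed maturation genes rose from low levels, such as EM1 (0.406 ± 0.0780 to 3.20 ± 0.655 CPM) and SESA2 (2.64) (camera adjusted p = 0.0294, but adjusted p = 0.905 with an estimated correlation). The third, SESA1, was not called without rh27-2 replicate 1 (adjusted p = 0.0547) or 2 (0.0653). Counts adjusted over the list alone were the same for these 5 lists. They were the lists that passed camera in shoot apices; 9 passed without wild-type replicate 3.

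Small RNA genes went both ways in shoot apices. Of 15 tested pri-miRNA loci 1 rose and 1 fell (camera adjusted p = 0.823): MIR414 went from 9.15 ± 0.259 to 1.70 ± 0.847 CPM (-2.43), and MIR863 rose by 1.03, a call that was lost without rh27-2 replicate 2 (adjusted p = 0.0902) or 3 (0.0668), or wild-type replicate 2 (0.0650) or 3 (0.0537). Of 24 genes of miRNA biogenesis and action, 5 fell and none rose (0.216): AGO10 (-1.2, from 110 ± 22.5 to 47.9 ± 3.83 CPM), TGH (-0.84), CBP20 (-0.46), DDL (-0.69) and ABH1 (-0.33). CBP20 and DDL were not called without rh27-2 replicate 2 (adjusted p = 0.0568 and 0.0532) or 3 (0.0576 and 0.0601). DCL1 was not called. Of 13 genes of other small RNA pathways 4 fell, led by RDR6 (-0.57), and NRPD1 rose (0.55) (list adjusted p = 0.427). Among 78 canonical miRNA targets 14 rose and 20 fell (15 and 20 adjusted over the list alone; camera adjusted p = 0.178, and 0.0313 without wild-type replicate 2). The lower ones included the leaf growth regulators TCP4 (-3.79, from 52.9 ± 7.63 to 3.84 ± 1.12 CPM), TCP2 (-2.82, from 39.9 ± 6.41 to 5.65 ± 0.746 CPM), GRF1 (-2.77, from 42.4 ± 7.92 to 6.23 ± 0.627 CPM) and GRF9 (-2.26). All these tests were edgeR or camera with Benjamini-Hochberg adjustment.

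Of 12 shoot meristem genes, 7 rose and 2 fell, with STM (2.27), KNAT1 (1.85, from 29.0 ± 8.18 to 104 ± 21.4 CPM), KNAT6 (1.21) and BLH9 (0.95) among the higher and CRN (-1.24) and CLV1 (-0.47) as the lower (camera adjusted p = 0.109, and 0.0232 without wild-type replicate 3). In the lateral organ list 2 of 12 rose (3 adjusted over the list alone) and 3 fell (adjusted p = 0.789): YAB1 (-1.25, from 95.6 ± 4.67 to 40.2 ± 4.03 CPM), YAB3 (-1.04) and AS1 (-0.83) fell, and BOP1 (1.3) and DRNL (1.74) rose. The median and mean of that list were positive while the test pointed down. Of 17 CDK inhibitor and DNA damage genes 8 rose and 3 fell (camera adjusted p = 0.109; 0.0404 without wild-type replicate 1). The stress transcription factor NAC044 rose from 3.01 ± 1.51 to 34.8 ± 5.05 CPM (3.52) and its paralogue NAC085 by 4.57, KRP6 by 1.38 and SMR4 by 1.68, while KRP4 (-1.27), KRP3 (-1.42) and PARP1 (-0.41) fell. Of 8 cytokinin response regulators 4 fell (adjusted p = 0.216), including ARR16 (-3.25) and ARR7 (-2.05, from 46.5 ± 19.8 to 11.3 ± 1.84 CPM). Auxin response genes went both ways, with 4 of 16 higher and 5 lower (0.789), for example GH3.1 (2.27) and GH3.3 (-2.44), and 2 of 6 auxin transport genes fell (0.776), one of them PIN4 (-1.22).

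Ribosome lists hardly moved in shoot apices. Beside NUC2, 1 of the 25 ribosome biogenesis genes rose (camera adjusted p = 0.654), and that 1, FIB2 (0.37), was not called when adjusted over the list alone or without rh27-2 replicate 2 (adjusted p = 0.138), among other libraries. Of 23 cytosolic ribosomal protein genes 1 fell (0 adjusted over the list alone; list adjusted p = 0.556). DNA replication had 2 of 13 lower (0 adjusted over the list alone; list adjusted p = 0.352, and 0.0448 without wild-type replicate 3). In the immune and jasmonate list 2 of 9 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.821, and 0.0276 without wild-type replicate 3). PR5 (-5.93, from 15.8 ± 5.65 to 0.235 ± 0.226 CPM) fell with LOX2, and JAZ1 (1.24) rose, with a positive median and a negative mean over the list. Hypoxia genes had 3 of 9 higher (0.298), namely PCO2 (1.43), PDC1 (1.59) and SUS4 (1.72). Heat shock had 3 of 5 higher (4 adjusted over the list alone), led by HSP18.2 (1.42), with a list adjusted p of 0.178 and of 0.0366 with the replicate number as a block. Flavonoid genes had 3 of 9 lower (0.360, and 0.00140 without wild-type replicate 3), led by MYB75 (-1.2), and none of 6 phosphate starvation genes passed (0.607). Lists of root cell types held few tested genes here: root stem cell niche 1 higher and 2 lower of 7 (0.821), endodermis 1 and 1 of 3 (2 and 1 adjusted over the list alone; 0.556), root hair and epidermis 0 and 1 of 3 (0.776), and the single root cap gene CEL5 was not called (-0.07; list 0.902).

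In mutant root tips, 24 of 25 ribosome biogenesis genes, 8 of 9 hypoxia genes and 7 of 13 stem cell niche genes rose, while all 10 root hair and epidermis genes and all 6 endodermis genes fell. NUC2 went from 3.14 ± 0.878 to 83.5 ± 5.61 CPM (4.76, SE 0.13; adjusted p = 4.13e-10, edgeR), and NAC044 from 2.30 ± 0.167 to 85.4 ± 1.72 CPM (5.21, SE 0.086; adjusted p = 2.03e-13). The Casparian strip gene CASP1 fell by 1.08 (SE 0.058). Of 19443 tested genes 6076 were higher and 5999 lower, which is 62.1% of them against 40.9% in shoot apices, and 1953 and 1243 changed at least 2-fold. The biological coefficient of variation was 0.0735 in root tips and 0.202 in shoot apices, so smaller changes could be called in root tips. Scaling to total counts gave 7291 higher and 4834 lower genes in root tips.

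The largest rises among named genes in root tips included BCAT4, an aminotransferase of methionine chain elongation (8.06, SE 0.59; 0.454 ± 0.117 to 124 ± 49.0 CPM), the sulfate transporter gene family member SULTR3;5 (7.23, from 0.112 ± 0.0814 to 19.0 ± 3.07 CPM), EARLI1 (8.46) and the lipid transfer protein LTP5 (7.09). PER1 and EM1, proteins of maturing seeds, had no count in any wild-type root library and reached 7.87 ± 1.95 and 7.53 ± 3.69 CPM in rh27-2, at least 132-fold and 126-fold higher than the floor of 3 counts over the group. The seed regulator ABI3 went from 0.0439 ± 0.0761 to 5.30 ± 0.695 CPM. Among the falls, the asparagine synthetase ASN1 went from 213 ± 58.0 to 3.52 ± 1.08 CPM (-5.91), the transporter UMAMIT17 from 65.1 ± 2.62 to 2.77 ± 0.236 CPM (-4.55), the ethylene synthesis gene ACS5 from 36.2 ± 4.30 to 1.83 ± 0.162 CPM (-4.30) and the sulfate transporter SULTR1;1 from 20.5 ± 5.32 to 1.56 ± 0.265 CPM (-3.71). The MADS-box gene AGL42 went from 12.3 ± 0.724 to 0.0356 ± 0.0309 CPM.

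Of 25 ribosome biogenesis genes 24 rose in root tips, among them PUM24 (0.98, from 50.6 ± 2.17 to 99.8 ± 6.34 CPM), NOP56 (0.88, from 263 ± 19.1 to 484 ± 27.7 CPM) and RRP5 (0.86), and the exception was RH7 (-0.18) (camera adjusted p = 7.98e-10, but adjusted p = 0.601 with an estimated correlation). Of 23 ribosomal protein genes 20 rose, such as RPS27B (0.67) and RPL4D (0.53), and RPL3B fell (-0.59) (camera adjusted p = 0.0105, but adjusted p = 0.808 with an estimated correlation). Hypoxia genes rose in 8 of 9 cases, including the haemoglobin HB1 (2.79, from 5.30 ± 0.351 to 36.6 ± 2.28 CPM) and the pyruvate decarboxylase PDC1 (2.31, from 8.98 ± 0.193 to 44.6 ± 4.48 CPM) (camera adjusted p = 1.41e-04, but adjusted p = 0.235 with an estimated correlation). In the root stem cell niche list 7 of 13 rose and none fell, led by PLT3 (1.98, SE 0.064), WOX5 (2.93), BRAVO (1.2) and BBM (1.11) (camera adjusted p = 0.00685, but adjusted p = 0.618 with an estimated correlation). Seed maturation genes were higher in 5 of 6 cases (camera adjusted p = 0.00512, but adjusted p = 0.501 with an estimated correlation), for example EM6 (3.37). All 10 root hair and epidermis genes fell, including COBL9 (-1.21, from 132 ± 8.58 to 56.9 ± 1.07 CPM), EXPA7 (-1.29) and the non-hair regulators GL2 (-1.67) and WER (-1.17) (camera adjusted p = 1.61e-07, but adjusted p = 0.235 with an estimated correlation). All 6 endodermis genes fell, with CASP1 to CASP4 between -1.08 and -1.16 (camera adjusted p = 4.46e-06, but adjusted p = 0.235 with an estimated correlation).

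**Figure D2:**
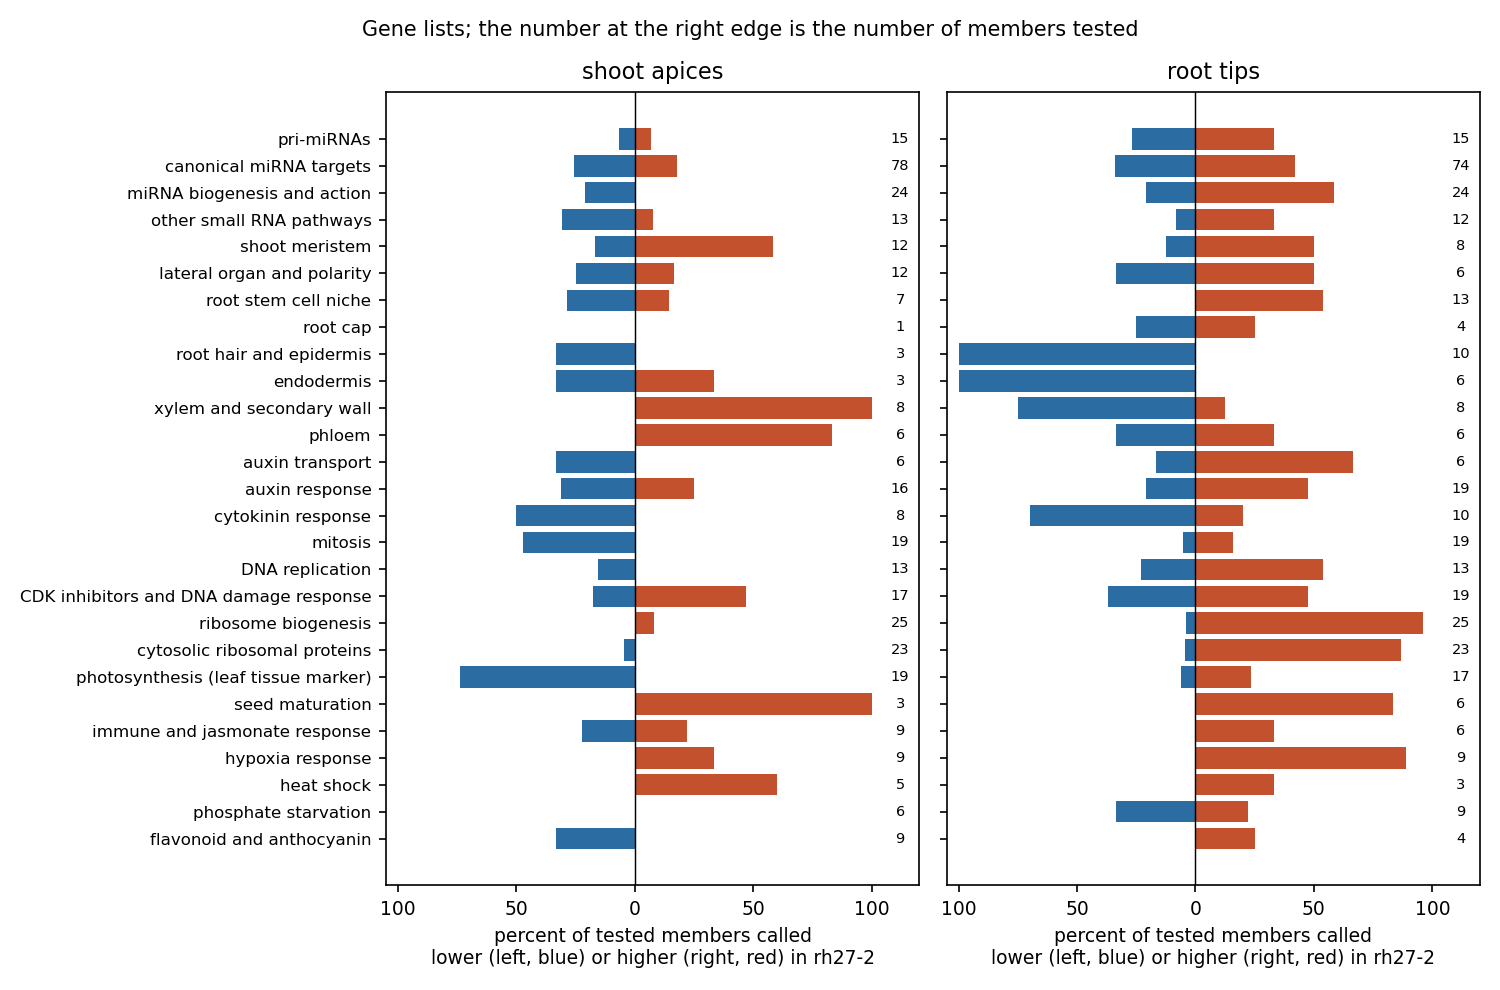
Percent of the tested members of each gene list (vertical axis) that were called lower (blue, to the left) or higher (red, to the right) in rh27-2 (horizontal axes), for shoot apices on the left and root tips on the right, with the number tested at the right edge. All 8 xylem genes were higher in shoot apices, and 24 of 25 ribosome biogenesis genes were higher and all 10 root hair genes lower in root tips.

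Other root lists were mixed. Of 15 pri-miRNA loci 5 rose and 4 fell (camera adjusted p = 0.680): MIR163 went from 40.4 ± 2.64 to 10.2 ± 1.15 CPM (-1.98), MIR162a (-0.64), MIR830 (-1.44) and MIR319b (-1.11) also fell, MIR5642a (1.58), MIR775 (2.27) and MIR824 (1.32) rose, and MIR5023 and MIR156c were near the floor in wild type. Of 24 genes of miRNA biogenesis and action 14 rose and 5 fell, all modestly (0.402), for example STA1 (0.40), SDN2 (0.56) and CPL1 (0.39) against URT1 (-0.51). Other small RNA pathways had 4 of 12 higher and 1 lower (0.679), with AGO2 (0.55) and NRPD1 (0.81) higher; the single lower gene, RDR6, was not called without rh27-2 replicate 2 (adjusted p = 0.0579). Of 74 canonical miRNA targets 31 rose and 25 fell (0.342), from the sulfate transporter SULTR2;1 (5.49, from 1.46 ± 0.291 to 66.6 ± 1.97 CPM), PHO2 (1.06, from 121 ± 11.8 to 252 ± 4.40 CPM), ARF6 (0.87) and HB8 (0.84) among the strongest. CDK inhibitor and DNA damage genes had 9 of 19 higher and 7 lower (0.0541), NAC044 and BRCA1 (1.18) among the higher. DNA replication had 7 of 13 higher and 3 lower (0.402), with RNR1 highest (0.97, from 85.9 ± 2.67 to 168 ± 9.06 CPM), and mitosis 3 of 19 higher (2 adjusted over the list alone) and 1 lower (0.804), the median being slightly negative and the mean slightly positive, with CYCB1;1 (0.69) and HIK (0.44) higher and CYCB2;3 (-0.31) lower. All these were edgeR and camera values with Benjamini-Hochberg adjustment.

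Xylem genes in root tips fell in 6 of 8 cases and 1, VND6 (1.23), rose (camera adjusted p = 0.0768; 0.00939 without wild-type replicate 2), with LAC4 (-0.69) and CESA4 (-0.73) as examples. Phloem had 2 of 6 higher, CALS7 (0.79) and NAC86 (1.23), and 2 lower, SUC2 (-1.80) and SEOR1 (-0.84) (adjusted p = 0.980). Of 10 cytokinin regulators 7 fell and 2 rose (0.230), ARR15 (-2.67) and ARR5 (-0.90) against ARR7 (1.81). Auxin response had 9 of 19 higher and 4 lower (0.562), with GH3.3 (3.32) higher and IAA3 (-1.49) lower, and auxin transport 4 of 6 higher and 1 lower (0.809), with PIN4 as the lower one (-1.81, from 145 ± 6.38 to 41.3 ± 4.33 CPM). Of shoot meristem genes 4 of 8 rose and 1 fell (0.349), KNAT1 (1.95) and LAS (1.56) against BLH9 (-0.93), and of lateral organ genes 3 of 6 rose and 2 fell (0.562), ANT (2.63) against KAN1 (-0.85). Phosphate starvation genes went both ways, 2 of 9 higher and 3 lower (0.402), with PHT1;4 (1.66) against SQD2 (-1.48) and MGD2 (-2.28). Photosynthesis had 4 of 17 higher and 1 lower (0.562, and 0.0335 without rh27-2 replicate 3), all 4 from below 0.4 CPM. The lists of immune and jasmonate genes (2 of 6 higher, VSP2 at 2.39; 0.402), root cap (1 higher and 1 lower of 4, BRN1 at 0.33 and CEL5 at -0.56; 0.683), heat shock (1 of 3 higher; 0.708) and flavonoids (1 of 4 higher; 0.528) did not pass camera. The single heat shock call, HSP18.2, was lost without wild-type replicate 1 (adjusted p = 0.0888) or 2 (0.0524) or rh27-2 replicate 3 (0.0742), and the flavonoid one, CHS (1.43), without wild-type replicate 3 (0.0506).

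Mature miRNA levels are given as deposited, in reads per 30000000 (RP30M), and tested with limma on the log2 scale after adding 1. In shoot apices the miR845 entries rose most: miR845a went from 417 ± 225 to 27038 ± 3836 RP30M (6.14, SE 0.35; adjusted p = 8.66e-48, limma) and miR845b from 1.80 ± 2.1 to 996 ± 250 RP30M. miR158b (2.24), miR822-3p (1.70), miR396b-5p (1.35, from 1285 ± 755 to 2938 ± 196 RP30M) and the abundant miR408-3p (1.13, from 39004 ± 8810 to 84587 ± 13437 RP30M) rose too. The entries miR167b (-3.73, from 2730 ± 806 to 200 ± 16.7 RP30M), miR3932b-5p (-3.33), miR167a-3p (-2.82), miR399c-3p (-2.71) and miR171a-3p (-1.57) fell. Below the abundance set for naming entries, and picked after their values were seen, miR829-3p.1 rose from 1.81 ± 1.23 to 45.4 ± 14.0 RP30M (4.08) and miR399a fell from 53.5 ± 27.3 to 2.61 ± 2.26 RP30M (-4.13). Among the most abundant entries, miR398c-3p (0.07), miR165b (0.09) and miR161.1 (0.11) did not pass the test. Of 79 tested entries 16 were higher and 19 lower. The split was 9 to 26 after scaling to the total of the listed miRNAs, 22 to 15 with TMM scaling, 20 to 15 with DESeq2's size factors and 27 to 21 in DESeq2. Without any 1 of the rh27-2 libraries 7 entries were higher, without wild-type replicate 3 it was 8, and without wild-type replicate 2 it was 23, with 12 lower.

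Summed by family in shoot apices, 10 of 44 families were higher and 8 lower (limma). The family miR829, also picked after its values were seen, rose from a low level (4.13, from 2.24 ± 0.921 to 56.7 ± 19.8 RP30M; adjusted p = 4.53e-29). miR845 (6.18) and miR408 (1.09) rose, and miR167 (-3.17, from 5439 ± 839 to 602 ± 82.8 RP30M), miR3932 (-3.33), miR399 (-2.64) and miR171 (-1.51, from 4116 ± 1325 to 1402 ± 126 RP30M) fell. miR396 (1.08) was not called without rh27-2 replicate 3 (adjusted p = 0.0531). Leaving out any 1 rh27-2 library left 3 higher families, and leaving out rh27-2 replicate 1 or 3 left 5 or 4 lower ones, while 16 were higher without wild-type replicate 2. The split was 7 to 17 with scaling to the listed miRNAs, 17 to 8 with the upper quartile and 9 to 13 with edgeR on library depth. Set beside their listed targets, the family miR167 was lower and both of its targets, ARF6 and ARF8, were higher (0.91 and 0.72, picked after their values were seen). miR396 was higher and 5 of its 7 GRF targets were lower. miR319 did not pass the test (0.56; adjusted p = 0.137), although it did with TMM in limma (0.75, adjusted p = 0.00122) and without wild-type replicate 2 (0.83, adjusted p = 0.00148), while all 5 tested TCP targets were lower. Of the 11 called families with listed targets, miR167, miR394, miR396 and miR827 had called targets in the opposite direction only. miR164 and miR166 had them in the same direction only, with 3 of 5 and 1 of 5 targets higher. The other 5, miR171 and miR399 among them, had no called target. Among these 5, miR157 (0.83, adjusted p = 0.0257, limma) also stood for miR156, which was not called (0.29, adjusted p = 0.434). The entry miR157b-3p held a mean of 14933 of the 15398 RP30M of miR157. Likewise miR824-3p held 2180 of the 2194 RP30M of miR824. For these families the tally does not show that the miRNAs acting on the targets changed. The call of miR164 was lost without rh27-2 replicate 1 (adjusted p = 0.0752) or 2 (0.0811), and that of miR394 without rh27-2 replicate 1 (0.0588) or 3 (0.0531). miR827 was not called without wild-type replicate 3 (0.0575) or rh27-2 replicate 1 (0.0729) or 3 (0.0907). miR166 was not called without wild-type replicate 3 (0.186) or any 1 rh27-2 library.

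Root tips also showed a miR845 rise, with miR845a at 391 ± 39.9 RP30M in wild type and 136839 ± 29387 RP30M in rh27-2 (8.43, SE 0.30; adjusted p = 6.76e-104, limma), and otherwise mostly lower values on the deposited scale. miR859 (3.21), miR5028 (2.98, from 634 ± 135 to 5076 ± 1484 RP30M), miR827 (2.67), miR158b (2.38, from 2289 ± 552 to 11984 ± 3313 RP30M) and miR408-3p (1.89) rose. miR172b-3p (-3.42), miR156f-3p (-2.86, from 895 ± 202 to 121 ± 21.7 RP30M), miR160c-3p (-2.75), miR390b-3p (-2.26) and miR846-5p (-2.16, from 2971 ± 610 to 715 ± 381 RP30M) fell. At lower abundance, and picked after their values were seen, miR8184 rose from 0.616 ± 1.07 to 70.6 ± 18.0 RP30M (5.63) and miR780.1 fell from 114 ± 41.2 to 3.69 ± 1.90 RP30M (-4.63). Of 125 tested entries 16 were higher and 73 lower, with a median of -0.96. That balance rested on the scaling: it was 36 to 46 with TMM in limma, 41 to 37 with DESeq2's size factors, 54 to 30 with TMM in edgeR, 53 to 39 in DESeq2, 29 to 68 with the listed total and 30 to 63 with the upper quartile. The median was -0.21 with TMM in limma and 0.06 with TMM in edgeR. The most abundant entries depended on it as well: miR161.1 was at -0.26 (adjusted p = 0.511, limma) as deposited and at 0.46 with TMM in limma, and miR157b-3p fell as deposited (-0.92) but not with TMM in limma (-0.20, adjusted p = 0.130), nor without wild-type replicate 3 (0.0917) or rh27-2 replicate 2 (0.0802). miR159a fell as deposited (-1.27) and was at -0.25 with TMM in edgeR (adjusted p = 0.129). miR158a-3p did not pass (-0.65, adjusted p = 0.0810), did so with the replicate number as a block (adjusted p = 0.00448) or without rh27-2 replicate 3 (0.00251), and was higher with TMM in edgeR (0.35).

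Of 70 root families 11 were higher and 40 lower (limma), with a median of -1.0; with TMM in limma the split was 30 to 26 and the median -0.06, with the upper quartile 22 to 28, with DESeq2's size factors 27 to 27, with edgeR and TMM 35 to 25, with DESeq2 37 to 27 and without a filter 23 to 50. Falls of about that median on the deposited scale are therefore not falls relative to the other families. Families beyond it included miR780 (-4.75), miR8182 (-3.36), miR172 (-2.23) and miR846 (-1.98, from 63973 ± 8954 to 16708 ± 5355 RP30M), and the family miR158 was at -0.59 as deposited (adjusted p = 0.127; 0.00794 with the replicate number as a block, 0.00464 without rh27-2 replicate 3) and at 0.32 with TMM in limma. Among families with listed targets, miR397 was higher from a low level (1.77 ± 1.85 to 50.7 ± 21.9 RP30M) and both tested laccase targets were lower, including LAC4 (-0.69). LAC4 also belongs to the xylem list, of which 6 of 8 genes fell in root tips, so its fall cannot be credited to miR397. miR169 was lower (-1.76; not called with TMM in limma, -0.85, adjusted p = 0.0916) with 5 of its 6 tested NF-YA targets higher and 1 lower. miR162 was lower (-1.79) with its target DCL1 slightly higher (0.23). miR393 was lower (-1.61) with 3 of its 4 tested targets lower too. These family values were mostly reads of single entries, picked after their values were seen. miR169f-3p held a mean of 3078 of the 3216 RP30M of miR169, and miR393b-3p 538 of the 566 of miR393. The scarcer entries miR169a-5p (-1.59) and miR393b-5p (-1.86) were lower too. Which arm of a precursor acts on the targets was not tested. Of the 21 families with listed targets that were called on the deposited scale, 8 had called targets in the opposite direction only. Another 6 had them in the same direction only (miR157, miR159, miR163, miR319, miR393 and miR827). A further 6 had them in both (miR164, miR169, miR171, miR172, miR396 and miR408) and 1 had none. Here miR157 also stood for miR156, which shares its listed targets and was itself not called (-0.09, adjusted p = 0.810, limma). The entry miR157b-3p held a mean of 94379 of the 99486 RP30M of miR157. The tally therefore does not show that the miRNAs acting on these shared targets changed. The call of miR157 was lost without wild-type replicate 3 (adjusted p = 0.0956) or rh27-2 replicate 2 (0.0763), and its direction turned with TMM in edgeR (0.03). miR167, 1 of the 8, was lower as deposited (-0.83) but not with DESeq2's size factors (0.02), in DESeq2 (0.03) or with TMM in limma (0.07) or edgeR (0.12). The call of miR164 was lost with TMM in limma (-0.24, adjusted p = 0.0840). miR163 (-1.32) and its precursor transcript MIR163 (-1.98) were both lower, and MIR162a and MIR319b fell with the families miR162 and miR319. In contrast, MIR775, MIR824 and MIR5642a rose while their families were not called. Those families were miR775 (-0.57, adjusted p = 0.0872, limma), miR824 (-0.31, 0.347) and miR5642 (0.57, 0.147). Whether mature levels follow their precursor transcripts was not tested.

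**Figure D3:**
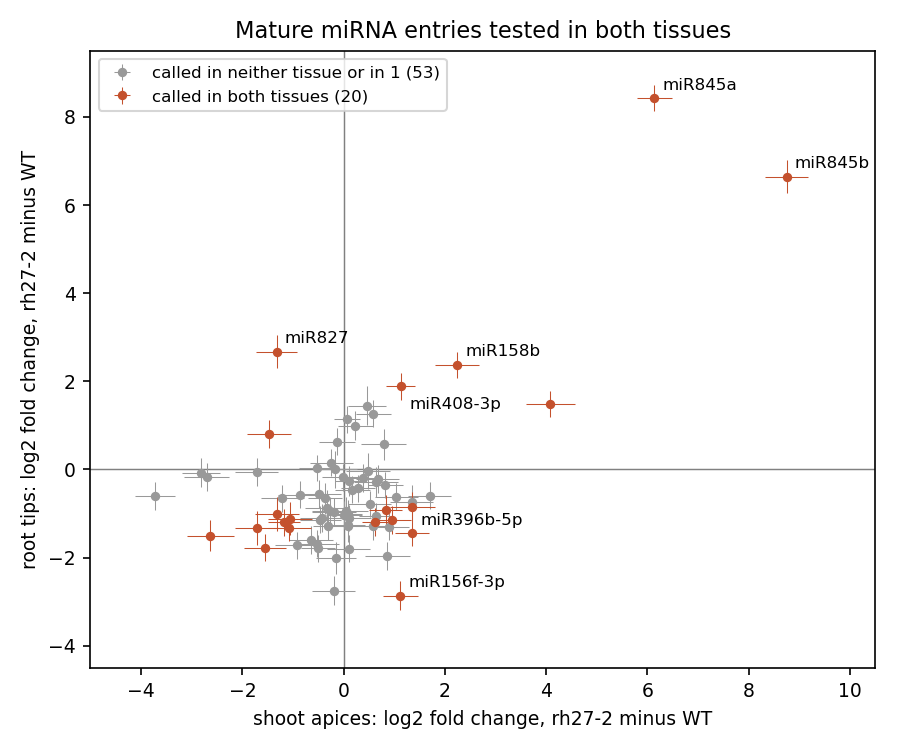
Log2 fold changes of rh27-2 against wild type on the deposited scale for the 73 miRNA entries tested in both tissues, shoot apices on the horizontal and root tips on the vertical axis. Points are limma estimates with SEs as error bars, red where the entry was called in both tissues (20 entries); miR845a and miR845b lie far above the others in both tissues.

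The listed miRNAs made up 2.25 ± 0.371% of the reads of wild-type shoot apices and 2.71 ± 0.210% of those of rh27-2 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow), and 2.25 ± 0.370% and 2.61 ± 0.200% without the miR845 entries (two-sided exact permutation p = 0.2). In root tips the shares were 4.08 ± 0.715% and 3.04 ± 0.810% (two-sided exact permutation p = 0.2), and 4.08 ± 0.715% and 2.58 ± 0.764% without the miR845 entries (two-sided exact permutation p = 0.1). By replicate number, which was taken to pair these root libraries, the share was lower in rh27-2 in all 3 pairs, with and without miR845 (exact sign-flip p = 0.25 for both, the smallest that 3 pairs allow). What the 30000000 reads of the scale count over is not given in the sources used here.

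The tissues shared part of their changes and differed in many. Of 17692 genes tested in both, 1535 were higher in both tissues against 1160 for independent lists (odds ratio 1.76, one-sided Fisher's exact test p = 4.14e-49), and 1143 were lower in both against 1014 (odds ratio 1.25, p = 5.06e-08). Another 1746 were called in opposite directions, against 2169 for independent lists. The Fisher p-values treat genes as independent, which they are not, and do not measure the spread between libraries. Across the same genes Spearman's rho between the log2 fold changes of the tissues was 0.15. NUC2, NAC044 and miR845 rose in both tissues. In the test of the difference between tissues, 4460 genes had a higher change in root tips than in shoot apices and 4699 a lower one (edgeR interaction over 12 libraries, 20798 genes), of which 4114 and 4314 had been tested in both tissues. Total count scaling gave 6883 and 3321, since it moved the median difference of all genes from 0.06 to 0.29, and it moved the median gene to -0.11 in shoot apices and 0.10 in root tips.

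The genes with the strongest evidence for such a difference were CDEF1, which fell by 10.46 in shoot apices and rose by 2.95 in root tips, ANNAT4 (1.93 and -2.99), PRR1 (1.76 and -0.83) and GXMT1 (2.01 and -0.55), and RRA1, which fell in shoot apices (-4.13) and did not pass the test in root tips (0.41). Lists whose changes differed between the tissues by camera were xylem (median difference -1.93, adjusted p = 2.78e-11; adjusted p = 0.178 with an estimated correlation), phloem (-1.40, 3.30e-04; 0.367), ribosome biogenesis (0.58, 4.45e-05; 0.729), photosynthesis (1.61, 8.54e-05; 0.729), mitosis (0.91, 0.0140; 0.729), ribosomal proteins (0.40, 0.0140; 0.729) and miRNA biogenesis (0.32, 0.0402; 0.729), with the adjusted p for an estimated correlation given second each time. Among 132 miRNA entries 13 had a higher and 40 a lower change in root tips (limma). Only 7 and 25 of these had been tested in both tissues. The other 21 were below the filter in at least 1 tissue, and for the 5 of them that were absent from every library of 1 tissue the value is the change in the other tissue alone. Other choices gave 24 and 23 with DESeq2's size factors, 25 and 12 with TMM in limma, 24 and 21 with the listed total, and 29 and 24 in DESeq2. On the deposited scale miR396b-5p, for example, rose in shoot apices (1.35) and fell in root tips (-1.44), a difference of -2.79.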

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

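The results below were picked out because the effect of the genotype differed between the tissues in an interaction test. In the weighing of the 3 patterns, the tests of leaf primordium share, of depth, of the scaling and of the genes on chromosome 5 were chosen only after the result was seen, as was the count on a single chromosome as the deciding value.

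In the interaction test, 4460 genes had a higher and 4699 a lower log2 fold change in root tips than in shoot apices (edgeR), as had 13 and 40 miRNA entries (limma). Of these, 4114 and 4314 genes and 7 and 25 entries had been tested in both tissues, and the other 21 entries were below the filter in at least 1 tissue. For the 5 of them that were absent from every library of 1 tissue, the value is the change in the other tissue alone and no difference of 2 measured effects. Only 1 of 100 drawn splits within tissues, the real one, gave as many genes, with 9159 calls against at most 3165 in the others, and only 1 gave as many miRNA entries, with 53 against at most 39. These splits undo the genotype effect of a tissue as well, so chance can be excluded only for counts that arise with no genotype effect, and not for the difference of that effect between the tissues. The highest other counts came from the 14 splits that kept the genotypes parted in one tissue, and the 85 that parted them in neither gave 0.

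The genes that led this test were CDEF1 (root minus shoot 13.4), PRR1 (-2.65), GXMT1 (-2.62), ANNAT4 (-4.98) and RRA1 (4.48). The miRNA entries called in opposite directions were miR156f-3p (-3.98), miR827 (3.99), miR396b-5p (-2.79), miR164b-5p (-2.10), miR166g (-1.81), miR5026 (2.29), miR157b-3p (-1.75) and miR396b-3p (-2.21). These directions hold for the deposited scale. The root falls of miR164b-5p (-1.15), miR166g (-1.19), miR157b-3p (-0.92) and miR396b-3p (-0.85) lay near the median of all root entries there (-0.96). That median was -0.21 with TMM in limma, so these 4 are not shown to fall relative to the other entries. The interaction of miR157b-3p and of miR396b-3p was not called with TMM scaling in limma. In shoot apices, miR156f-3p was not called without wild-type replicate 3 (adjusted p = 0.0662), miR827 without wild-type replicate 2 (0.0870) or 3 (0.0803) or rh27-2 replicate 3 (0.0552), miR5026 without rh27-2 replicate 3 (0.0992), miR396b-3p without rh27-2 replicate 3 (0.0786), and miR166g without wild-type replicate 3 (0.279) or rh27-2 replicate 1 (0.118), 2 (0.141) or 3 (0.119). In root tips miR157b-3p was not called without wild-type replicate 3 (0.0917) or rh27-2 replicate 2 (0.0802). The gene lists were xylem and secondary wall (median difference -1.93), phloem (-1.40), photosynthesis (1.61), mitosis (0.905), ribosome biogenesis (0.580), cytosolic ribosomal proteins (0.398) and miRNA biogenesis and action (0.323), none of which was called with an estimated correlation.

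Some genes were far lower in wild type than in rh27-2 in both tissues: 15 genes had a mean of at least 2 CPM in rh27-2 and under 5% of it in wild type, for example NDB4 (1.42 ± 0.342 to 97.0 ± 2.88 CPM in root tips) and AT2G18190 (0 to 27.9 ± 1.57 CPM in root tips). A strain variant against the reference, if carried by rh27-2, would also leave genes under 5% in rh27-2. The count of such genes was 0, which argues against a variant of that kind as the cause. That count could not show a variant carried by the wild-type plants, so no conclusion is drawn on that. A linked segment or a local rearrangement near the mutated locus would put the genes on chromosome 5, which holds RH27 (AT5G65900). That chromosome held the most of them, but that was 5 of the 15, so linkage is argued against for the 10 on other chromosomes. In locus order the 5 run from AT5G13210 to AT5G59390, with RH27 beyond them. Their distance from RH27 was not tested, so linkage was not decided for the 5. Among the 15 genes 0 pairs lay within 20 places in locus order, but the median random set also had 0. An effect of the genotype on these genes remains open and may apply, as a hypothesis found and tested on the same data. Whether other insertions or a second mutation are present was not tested.

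Most mature miRNAs were lower per 30000000 reads in mutant root tips, with a median ratio of 0.514. The mutant to wild-type ratio of mean sequencing depth was 0.943, against a relative SD of 0.0664 between wild-type libraries. Because RP30M values are already divided by this depth, the ratio could not have shown depth as the cause, and no conclusion is drawn from it. The scaling of the deposited values, whose total is not given, could account for part of it, but the other scalings cannot decide this. They centre most miRNAs near 0 by construction, so a near-even split would follow whether or not the class fell. As deposited, 16 entries were higher and 73 lower. The split was 36 and 46 with TMM in limma (56.1% lower) and 54 and 30 with TMM in edgeR. It was 41 and 37 with DESeq2's size factors and 53 and 39 in DESeq2. Whether miRNAs fell as a class or other small RNAs rose cannot be told apart, because the files hold no other small RNA. The miRNA share of the reads was lower in rh27-2 in all 3 replicate pairs, but the exact p was 0.25 for the pairs, 0.2 without pairing and 0.1 without pairing or the miR845 entries, so a biological difference in it stays open.

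Xylem and phloem markers were higher and light-harvesting genes lower in mutant shoot apices. A lower share of leaf primordium cells as the whole cause would lower the leaf lists alike, but the median of the lateral organ and polarity list, whose members went both ways, lay 1.21 above that of the photosynthesis list (SD of the lateral organ members 0.904). YAB1, YAB3 and AS1 of that list did fall, as did the leaf growth regulators TCP4 (-3.79), TCP2 (-2.82) and GRF1 (-2.77), so a lower share as part of the cause stays open. More vascular or stem tissue in the mutant samples remains a candidate explanation: of 11 further vascular markers not looked at before, 9 were higher and TMO5 lower (camera adjusted p = 0.00903; adjusted p = 0.477 with an estimated correlation), against 3 higher and 5 lower in root tips. A change of expression within cells cannot be separated from a change of tissue shares by these libraries, and was not tested.

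The splits of the 6 libraries of a comparison number 10, the real one included, too few for a share under 0.05. For genes the real split, 1 of the 10, gave 7769 calls in shoot apices and 12075 in root tips, and no other split gave any (highest other 0). For miRNA entries it gave 35 and 89 and for families 18 and 51, again 1 of 10 with a highest other of 0. For gene lists, 6 of the 10 splits gave as many camera calls as the real one in each tissue. The real split gave 5 in shoot apices (highest other 11) and 7 in root tips (highest other 10). Every other split mixes the genotypes unevenly, so part of the genotype difference stays in it and adds to the spread within groups. These splits therefore cannot tell how many camera calls arise with no effect. The 0 gene and miRNA calls in them can also follow from that spread. A camera call at the preset correlation stays weak evidence here, because none held with an estimated correlation. Where replicate numbers pair the samples, 4 of the 10 splits part all 3 pairs and 6 part 1 pair. Among those 4, the real split alone gave as many genes in shoot apices and as many miRNA entries and families in root tips, and 2 of the 4 gave as many gene lists in shoot apices (highest other 11), as did 4 of the other 6 (highest 9).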

How the results depend on the processing

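Of 7112 results for 416 named items and lists under the alternatives, 6688 (94.0%) kept their direction and side of the threshold, 316 were weaker, 89 stronger and 19 reversed. Many of these items were named for large or clear changes in the same data. The share therefore does not carry over to all genes and miRNAs, whose counts of calls moved more. The miRNA alternatives with TMM scaling, edgeR, other pseudocounts and filterByExpr were chosen after seeing the data, and where a result changed the cause was not tested unless stated.

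For genes in shoot apices, 6192 were higher with all 12 libraries in one fit; at an adjusted p under 0.01 there were 1968 higher and 1639 lower, and with an absolute log2 fold change of at least 1 there were 2050 and 1550, fewer by construction. In root tips the latter gave 1953 and 1243. Gene lists called were 0 and 0 with an estimated correlation in shoot apices and root tips (5 and 7 with the preset one) and 8 and 22 with fry, which asks another question. Total count only gave 6883 genes with a higher change in root tips. In the tissues alone it gave 3506 higher and 4656 lower genes in shoot apices, and 7291 and 4834 in root tips. The replicate numbers did not pair samples in the mRNA libraries of root tips (correlations 0.0412, 0.0229 and -0.0182) or the small RNA libraries of shoot apices (-0.260, -0.260 and -0.0821).

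For miRNA entries in shoot apices, 9 were higher with the listed total, 27 with DESeq2 and 10 at an adjusted p under 0.01. In root tips the higher and lower entries were 41 and 37 with DESeq2 size factors, 53 and 39 with DESeq2, 36 and 46 with TMM in limma, and 54 and 30 with TMM in edgeR; 29 were higher with the listed total, 30 with the upper quartile and 33 with no filter except 1 count. Reversed in root tips were miR158a-3p (0.35 with TMM in edgeR), miR157b-3p (0.063 with TMM in edgeR) and miR161.1 (0.57 with DESeq2 size factors, 0.28 with the upper quartile, 0.58 with DESeq2, 0.46 with TMM in limma, 0.73 with TMM in edgeR).

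For families in shoot apices, 17 were higher with the upper quartile and 17 with DESeq2, 5 at an adjusted p under 0.01 and 6 with an absolute log2 fold change of at least 1; 17 were lower with the listed total, 13 with TMM in edgeR, 13 with library depth in edgeR and 14 with all 12 libraries in one fit. In root tips, 27 were higher with DESeq2 size factors, 17 with the listed total, 22 with the upper quartile, 37 with DESeq2, 23 with no filter except 1 count and 17 with filterByExpr; with TMM 30 were higher and 26 lower in limma and 35 and 25 in edgeR. Reversed in root tips were the families miR158 (0.32 with TMM in limma, 0.37 in edgeR), miR157 (0.032 with TMM in edgeR), miR167 (0.023 with DESeq2 size factors, 0.027 with DESeq2, 0.073 with TMM in limma, 0.12 with TMM in edgeR) and miR161 (0.60 with DESeq2 size factors, 0.43 with the upper quartile, 0.60 with DESeq2, 0.65 with TMM in limma, 0.69 with TMM in edgeR). In the interaction of miRNA entries, the changes higher and lower in root tips were 24 and 23 with DESeq2 size factors, 24 and 21 with the listed total, 29 and 24 with DESeq2 and 25 and 12 with TMM in limma, and 20 were higher with the upper quartile.

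Leaving out 1 library at a time gave 2531 (without rh27-2 replicate 2) to 3789 higher and 1960 (without rh27-2 replicate 2) to 3908 lower genes in shoot apices, 2306 being lower without rh27-2 replicate 3, and 5653 to 5922 and 5494 to 5877 in root tips; gene lists 5 to 9 (without wild-type replicate 3) and 7 to 8; miRNA entries 7 (without any 1 rh27-2 library) to 23 (without wild-type replicate 2) higher and 12 to 16 lower in shoot apices, and 11 to 17 and 54 to 87 in root tips. Families ranged from 3 (without any 1 rh27-2 library) to 16 (without wild-type replicate 2) higher and from 4 (without rh27-2 replicate 3) to 10 lower in shoot apices, and from 8 to 11 and 29 to 46 in root tips. The difference in miRNA share ranged from 0.244 to 0.589 points in shoot apices and from -1.47 to -0.657 in root tips. In the simulation, 2-fold changes in shoot apices and in root miRNA entries were often missed. Far fewer features changed there than were called in the data, so it sets no limit for the data. Smaller changes were called as well: of 4007 higher genes in shoot apices, 2050 changed at least 2-fold.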

Other observations

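In root tips 9 of 12 genes of a mitochondrial dysfunction response and all 8 tested genes of aliphatic glucosinolate synthesis were higher, and in shoot apices 5 of 8 trichome genes were lower, but none of these lists passed camera with an estimated correlation. In root tips the glucosinolate genes MAM3 (5.06), CYP83A1 (6.73) and the regulator MYB28 (3.32) rose. Of the mitochondrial list, CRF6 (1.99) and UGT74E2 (2.78) rose there while AT12CYS-2 fell (-7.05), and UGT74E2 was not called in shoot apices (adjusted p = 0.230). In shoot apices GL1 (-6.32), which starts trichome formation, fell with TRY (-2.08) and GIS (-2.51).

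The 3 lists below and the further vascular list were written after the data had been seen but before their members' values were looked at, and the genes that prompted them (NDB4, BCAT4, SULTR1;1, MYB23 and GL2) were left out, while the correlation of families and targets was planned before its result was seen. A mitochondrial dysfunction response is a candidate explanation for the rise of NDB4: 9 of 12 members were higher in root tips and 3 lower (camera adjusted p = 0.00289; adjusted p = 0.0578 with an estimated correlation), the lower ones being AT12CYS-2 (8.00 ± 1.32 to 0.0528 ± 0.0516 CPM), UPOX (-1.46) and NDA2 (-0.42). In shoot apices 7 of 11 were higher and none lower (camera adjusted p = 0.00162; adjusted p = 0.284 with an estimated correlation). A rise of aliphatic glucosinolate synthesis in root tips may lie behind BCAT4, since 8 of 8 tested members were higher (camera adjusted p = 2.24e-14; adjusted p = 0.0578 with an estimated correlation), while in shoot apices 2 of 10 were higher, MYB28 (1.07) and MAM3 (1.77) (camera adjusted p = 0.298). A general fall of trichome genes may accompany MYB23: 5 of 8 members were lower in shoot apices (camera adjusted p = 0.00903; adjusted p = 0.284 with an estimated correlation). In root tips, which bear no trichomes, 6 of 7 were lower and 1 higher (camera adjusted p = 0.0167; adjusted p = 0.206 with an estimated correlation). Members such as GL3, EGL3, TRY, ETC1 and TTG1 also pattern the root epidermis, whose own list fell in all 10 cases, so the root count does not bear on trichomes. The fits behind these lists and the further vascular list did not use the replicate number as a block, although it was taken to pair the mRNA libraries of shoot apices. Among uncalled glucosinolate genes there, CYP79F2 and SUR1 were higher and MAM1 lower in rh27-2 within every replicate number. The cause of these changes was not tested.

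If targets moved against their miRNA family, the family changes and the median changes of their listed targets would correlate negatively. Across 24 families in shoot apices Spearman's rho was -0.379 (permutation p = 0.0691, adjusted p = 0.138 by Benjamini-Hochberg over both tissues; Pearson's r -0.369, p = 0.0773, adjusted p = 0.155, and -0.351 without the 2 families farthest out). Across 26 families in root tips rho was -0.106 (permutation p = 0.608, adjusted p = 0.608; r -0.136, p = 0.493, adjusted p = 0.493, and 0.231 without the 2 farthest). These are correlations across families, which are not independent replicates, from 100000 permutations, and neither passed its test. Each family value pools both arms, and a single family stood for those with shared targets.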
